A study of Caenorhabditis elegans with 10 samples.

How the data were processed

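Strand-specific libraries from poly(A)-selected RNA of sorted cells were sequenced, per the labels' protocols, with 5 libraries of YFP-labelled ASH neurons and 5 of cells without YFP. Groups were taken from the sample titles, which also number the libraries 1 to 5 within each group. FastQC, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks, Cuffdiff, HTSeq and DESeq2 are named in the submitters' processing notes, and per the labels differential expression was computed by the authors along 2 routes, Cufflinks with Cuffdiff and HTSeq with DESeq2. The genome build, the annotation, the counting rules for shared reads and the model settings were not given in the sources used here. No coordinates are printed for this reason.

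The analysis rests on the authors' deposited table of that comparison, which has 46273 rows, 1 of them a repeat that was dropped. The authors' group values are Cuffdiff FPKM, per the file headers and the form of the values, with 1 added by the authors to every value. The added 1 was subtracted here for every FPKM printed. There is 1 such value per group, so neither the depth of the libraries nor the spread between them could be derived, and no confidence interval is given. The log2 fold changes deposited by the authors come from both tools. Those of Cuffdiff equal the log2 ratio of the deposited group values, which hold the added 1, recomputed here to rounding, and so understate the change of low genes. Those of DESeq2 are the authors' fitted values, and whether they were shrunken is not given in the sources used here. The p-values and q-values deposited by the authors are those of each tool. The adjusted p of DESeq2 in the authors' deposited table equals a Benjamini-Hochberg adjustment over the 16802 genes that have one, and these are called tested here. They comprise 16086 protein-coding genes, 485 pseudogenes and 231 others. A further 3344 genes have a p without an adjusted p, and 1541 have a fold change without a p. The smallest Cuffdiff p in the table is 5e-05. A last column of the authors' deposited table repeats the DESeq2 adjusted p and is blank for 852 genes, all called by DESeq2 and not by Cuffdiff, while 15 other genes of that kind are not blank there. It was used only for this check. No columns of single samples were used, so no test of differential expression was run here and the authors' calls are summarised. The design had also foreseen tests on counts or values per library, which could not be run.

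Rows were matched by WormBase identifier to a table of current symbols, which held 43253 of the 46272 identifiers (93.5%). This also recovered 11 gene names that stand as dates in the table. A gene is called higher or lower at a DESeq2 adjusted p under 0.05 in the authors' deposited table, with the sign of the fold change. A total of 24 gene lists were fixed before the data were examined, and members were matched on the name in the table or the current symbol. Each list was compared with all other tested genes by Fisher's exact test, 1-sided in each direction, with Benjamini-Hochberg adjustment over the 48 tests. The median of the authors' DESeq2 log2 fold changes of the list was placed among the medians of 10000 random lists of the same size, matched on level in 20 bins, with 2-sided p adjusted over the 24 lists. Level is the mean FPKM of the 2 groups. The count adjusted over the list alone applies the Benjamini-Hochberg adjustment to the members' own DESeq2 p from the authors' deposited table.

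The rule for named genes was also fixed before the data were examined. It takes the 10 largest positive and the 10 largest negative DESeq2 fold changes past the threshold among genes above the median level, per the authors' deposited table. It adds every ASH gene, the 10 largest positive and up to 3 largest negative chemoreceptor genes past the threshold, and from each other list the 3 members past the threshold with the smallest adjusted p. For chemoreceptor genes the rule as fixed also held a limit on level, stated in counts. No limit on level was applied to them here. The rule as applied named 89 genes. The alternatives fixed in advance were a change of at least 2-fold, an adjusted p under 0.01, Cuffdiff's q, a floor of 5 FPKM in either group, pseudocounts of 0.1 and 5 for the FPKM ratio, and a background of genes above the median level. Alternatives chosen after the data were seen were genes called by both tools, protein-coding genes only, genes without the chemoreceptor families, list matching on the names in the table only, and the thresholds and Cuffdiff's q applied to the lists.

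The list tests were tested on simulated data of 16802 genes with the real lists and levels. In 40 simulations with 5.32% of genes called at random and a planted list of 30 genes with 30% called, Fisher's exact test recovered the planted list 35 times and called 2 of 960 unplanted lists. With a planted shift of 1 on the log2 scale, the random lists recovered it 40 times. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.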

Results

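RNA was profiled from cells of wild-type Caenorhabditis elegans sorted by fluorescence. ASH is a pair of polymodal sensory neurons in the head that detect noxious stimuli such as high osmolarity, touch and repellents. Cells carrying a YFP label for ASH made up 5 libraries, and cells without YFP, called non-ASH here, made up the other 5. The single comparison asked which transcripts were enriched in the sorted ASH neurons, in a series concerned with G protein-coupled receptor (GPCR) genes and osmosensation. The file analysed here held the authors' own comparison of the 2 groups, with 1 FPKM value per group and the fold changes and adjusted p of their 2 tools, so the values below carry no standard deviation and no n. Neither depth nor the spread between libraries could be read from it, and it gave no standard error for any fold change. Where nothing else is said, fold changes and adjusted p are those of DESeq2, the authors' count-based test, on the log2 scale and with ASH over non-ASH. Nothing in the labels says that the libraries came from separate cultures or sorts, so these adjusted p may measure a technical spread only.

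Genes with published expression or function in ASH were higher in the ASH fraction. The YFP transgene itself was listed at 1612 FPKM in ASH and 68.1 FPKM in non-ASH in the authors' deposited table, with a log2 fold change of 4.24 and an adjusted p of 1.3e-09. The cells were sorted on YFP, so this difference was set by the design and checks the sort only. Of 18 tested ASH genes, 10 were higher and 0 were lower, against 5.27% of all other tested genes being higher (Fisher's exact test, 1-sided, adjusted p = 8.2e-08). The largest fold change among them belonged to osm-10, required in ASH for avoidance of high osmolarity, at 142 FPKM in ASH and 1.12 in non-ASH with a log2 fold change of 5.34 (adjusted p = 1.77e-11) in the authors' deposited table. The TRPV channel genes ocr-2 and osm-9 had log2 fold changes of 3.53 (adjusted p = 1.57e-05) and 3.04 (adjusted p = 0.000416) in the authors' deposited table. The chemoreceptor gene sra-6 had 4.10, the homeobox gene unc-42 3.03 and the neuropeptide gene nlp-3 2.04 in the authors' deposited table. Among G protein alpha subunits, the authors' deposited table gave 3.54 for gpa-11, 3.02 for gpa-13 and 2.62 for odr-3, and the tenth gene past the threshold was the cilium gene osm-12, at 3.52 FPKM against 0.722. The other 8 did not pass, and the authors' deposited table listed them at 2.29 for gpa-3 (adjusted p = 0.0543), 1.88 for the vesicular glutamate transporter gene eat-4 (adjusted p = 0.0654), 1.46 for gpa-15, 1.21 for flp-21, 0.44 for dop-4, 0.40 for qui-1, -0.51 for tmc-1 and -1.07 for deg-1. Cuffdiff, the authors' other tool, called gpa-3 (q = 0.00101) and did not call sra-6, gpa-13 or osm-12 in the authors' deposited table. Adjusted over the list alone, 14 ASH genes were higher and 1 was lower. The members srb-6 and srv-11 had no adjusted p, with group values in the authors' deposited table of 0.375 and 0.0739 FPKM in ASH. The list median of 2.16 lay above that of every one of 10000 random lists matched on level (adjusted p = 0.0008, from an unadjusted p of 0.0002, the smallest that 10000 random lists can give in this 2-sided permutation test).

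**Figure D1:**
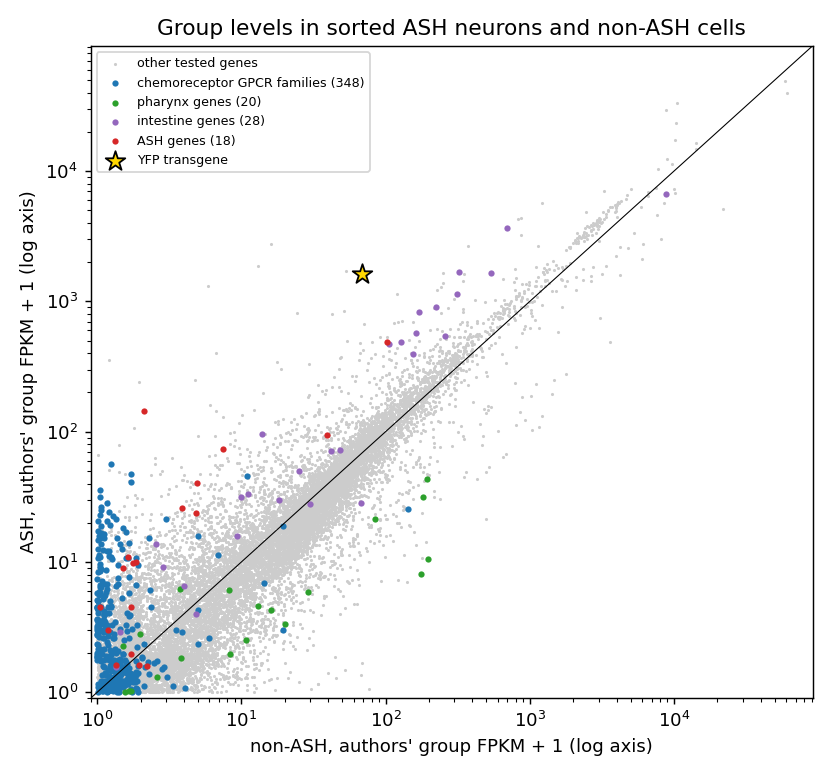
Authors' group FPKM plus 1 in ASH (vertical) against non-ASH (horizontal) for all tested genes, both on log axes, with 1 point per gene and a line of equality. The YFP transgene (1612 against 68.1 FPKM) and most ASH genes lie above the line, chemoreceptor genes rise along the left edge, intestine genes lie mostly above the line and pharynx genes mostly below it.

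In all, 16802 genes had an adjusted p, and 894 of them were higher in ASH and 746 lower at an adjusted p under 0.05 in the authors' deposited table. The row of the YFP transgene is among the 894. The median log2 fold change was 2.16 among the higher and -2.14 among the lower genes of the authors' deposited table. Among genes above the median level of 6.97 FPKM, the largest positive fold changes belonged to chemoreceptor genes and pseudogenes and to a few abundant transcripts. The most abundant were C10C5.7 with 2737 FPKM in ASH and 15.1 in non-ASH, M04B2.6 with 1870 and 12.1, and the neuropeptide gene C02B4.4, now named nlp-76, with 1311 and 4.92 in the authors' deposited table. Their log2 fold changes in the authors' deposited table were 7.15 (adjusted p = 7.51e-46) for C10C5.7, 6.90 (adjusted p = 2.84e-48) for M04B2.6 and 7.51 (adjusted p = 1.57e-32) for nlp-76. T23B3.6, with 239 FPKM against 0.957, had 7.06 in the authors' deposited table. The other 6 were the chemoreceptor genes srh-15 (7.53), sri-21 (7.06) and srw-102 (7.01) and the pseudogenes srh-29 (7.90), srw-131 (6.99) and srz-46 (6.87) of the same families, and Cuffdiff called none of these 6 in the authors' deposited table. The 10 largest negative fold changes included 2 genes of pharyngeal gland products, phat-3 (-4.31) and phat-4 (-3.92), and the collagen gene col-133 (-4.71) in the authors' deposited table. The remaining 7 were C45E5.4, now cpg-18 (-6.07), F41G3.21 (-4.81), T20G5.8 (-4.40), T24B8.5, now sysm-1 (-4.21), M163.8 (-4.12), pqn-60, now srlf-35 (-4.01), and ZK596.1, now srlf-30 (-3.97), all as the authors' deposited table gives them. Cuffdiff did not call cpg-18 (q = 0.552) or sysm-1 (q = 0.372) in the authors' deposited table.

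Chemoreceptor GPCR genes, the large nematode families of serpentine receptors, were the list with the most genes higher in ASH. Of 1632 chemoreceptor genes and pseudogenes in the table, 348 were tested, and 112 of these were higher in ASH and 2 lower, against 4.75% of other genes higher (Fisher's exact test, 1-sided, adjusted p = 5.03e-56). Adjusted over the list alone, 132 were higher and 7 lower. Whether a member was tested went with its level, the mean of both groups, with a median of 0.84 FPKM over the tested members and 0.0607 over the 589 with a p and no adjusted p in the authors' deposited table, and for genes near 0 in non-ASH that level is set by ASH. Over all protein-coding genes under 0.2 FPKM in non-ASH, tested or not, 100 of 1086 chemoreceptors (9.21%) and 177 of 3148 other genes (5.62%) were above 1 FPKM in ASH in the authors' deposited table, a comparison chosen after the data were seen (Fisher's exact test, 2-sided, p = 6.4e-05). The median log2 fold change was 1.23, above all random lists matched on level (adjusted p = 0.0008), and 1.05 over the 330 members listed above 0 in both groups. The genes higher in ASH were 16 of the 32 tested pseudogenes of these families and 96 of the 316 tested protein-coding members. Of the 10 members with the largest fold changes, srw-121 was listed at 13.8 FPKM in ASH and 0.00779 in non-ASH, with a log2 fold change of 8.18 (adjusted p = 1.77e-15), in the authors' deposited table. The gene srh-15 had 30.5 FPKM against 0.0409, and sri-25 had 11.6 against 0.0184 with a log2 fold change of 7.51, in the authors' deposited table. For srh-29, sri-21, srw-102 and srw-131 the authors' deposited table listed 19.8, 21.8, 25.6 and 14.3 FPKM in ASH. Non-ASH was listed at 0 for srw-139, srd-10 and srh-260, so that no ratio of FPKM can be formed. ASH stood at 4.13, 6.41 and 3.52 FPKM, and the DESeq2 log2 fold changes were 8.11, 7.27 and 7.19 in the authors' deposited table. Of these 10, srh-29, srw-131 and srh-260 are pseudogenes there. The 2 genes that were lower, sri-40 (142 FPKM in non-ASH, log2 fold change -2.48) and sra-14 (18.3 FPKM, -2.46), were more abundant in non-ASH than any of these 10 were there in the authors' deposited table. With Cuffdiff's q in place of DESeq2's adjusted p, 29 chemoreceptor genes were higher (Fisher's exact adjusted p = 0.000202), and 21 were higher by both. Reads may be shared among near-identical family members and pseudogenes, and the way the authors' counting treated them was not given in the sources used here, so single members are uncertain.

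Genes of the sensory cilium were also higher as a group. Of 45 tested genes for cilia and intraflagellar transport 12 were higher and 0 lower (Fisher's exact test, adjusted p = 3.24e-05), 43 had a positive fold change, and the median was 1.57, above all matched random lists (adjusted p = 0.0008). Adjusted over the list alone, 24 were higher. Those with the smallest adjusted p in the authors' deposited table were dyf-3 (18.9 FPKM against 7.83), the BBSome gene bbs-5 (log2 fold change 1.99) and the dynein gene che-3 (2.31), of which Cuffdiff did not call dyf-3 (q = 0.0952). The share was no longer past the threshold with a DESeq2 adjusted p under 0.01, where 2 of the 45 remained (Fisher's exact adjusted p = 0.945), nor among genes above the median level, where 4 members were left. Pan-neuronal genes did not differ as a group: 1 of 25 was higher, the median was 0.12 at the 77.1 percentile of random lists (adjusted p = 0.5), and adjusted over the list alone the count was also 1. That gene was unc-31, needed for dense core vesicle release, with 35.6 FPKM against 2.15 and a log2 fold change of 3.82 in the authors' deposited table.

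The lists of G protein, receptor and neuropeptide genes did not pass Fisher's exact test on DESeq2's calls, and single members did. Of 26 G protein subunit genes 5 were higher and 0 lower (Fisher's exact adjusted p = 0.0582; 7 higher adjusted over the list alone), with gpc-1, a gamma subunit, at 96.8 FPKM against 7.41 and a log2 fold change of 3.24 in the authors' deposited table, beside gpa-11 and odr-3 above. That list passed with Cuffdiff's q (Fisher's exact adjusted p = 0.00885) and at 2-fold (0.0414). Among 125 receptors for transmitters and neuropeptides 12 were higher and 7 lower (Fisher's exact adjusted p = 0.165 and 0.903; 14 and 9 adjusted over the list alone). The authors' deposited table gave npr-7 a log2 fold change of 3.66, the dopamine receptor gene dop-2 3.23 and frpr-19 1.68. That list passed on the higher side with Cuffdiff's q (Fisher's exact adjusted p = 0.0084) and among genes above the median level (Fisher's exact adjusted p = 0.000719). Of 140 neuropeptide precursor genes 12 were higher and 8 lower (Fisher's exact adjusted p = 0.305 and 0.849; 13 and 9 adjusted over the list alone), while the list median of -0.13 lay at the 0.23 percentile of random lists (adjusted p = 0.0105). With Cuffdiff's q 14 were higher (Fisher's exact adjusted p = 0.00342), and by both tools 9 were (0.0292). Besides nlp-76, nlp-59 stood at 1707 FPKM against 52.5 with a log2 fold change of 4.81 and nlp-55 at 675 against 69.3 with 3.09 in the authors' deposited table. By the names in the table alone, without current symbols, 5 of 109 neuropeptide genes were higher.

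TRP, TMC and piezo channel genes had 2 of 17 higher, ocr-2 and osm-9, and 1 lower, the TRPM gene gon-2 at -1.34 in the authors' deposited table (Fisher's exact adjusted p = 0.782 and 1; 2 and 3 adjusted over the list alone). Of 28 DEG/ENaC channel genes 2 were lower, del-6 (-1.79) and delm-2 (-2.90), with the values of the authors' deposited table and neither called by Cuffdiff (Fisher's exact adjusted p = 0.946; 0 higher and 3 lower adjusted over the list alone). Receptor guanylyl cyclases had 1 of 30 higher, gcy-4 (3.77), and 1 lower, gcy-28 (-1.40), in the authors' deposited table, and neither was called by Cuffdiff (the same counts adjusted over the list alone). Cuffdiff called 3 other members lower and 0 higher. The list median of -0.86 lay at the 0.15 percentile of random lists (adjusted p = 0.00853). None of the 27 tested genes typical of other sensory neurons passed the threshold in either direction, 0 by Cuffdiff's q and 0 adjusted over the list alone. Of 17 genes for other transmitters 1 was lower, also adjusted over the list alone. It was tbh-1, for octopamine synthesis, at 112 FPKM against 798 and a log2 fold change of -2.74 that Cuffdiff did not call (q = 0.349) in the authors' deposited table. Among 24 glutamate signalling genes 3 were lower (Fisher's exact adjusted p = 0.354; 1 higher and 6 lower adjusted over the list alone), the chloride channel gene avr-15 (-1.16) and the transporter genes glt-4 (-1.74) and glt-1 (-1.55) in the authors' deposited table. With a floor of 5 FPKM the 3 lower genes were among 9 tested and passed (Fisher's exact adjusted p = 0.0472). Cuffdiff did not call avr-15 there, and the list median was -1.08, at the 0.01 percentile of random lists (adjusted p = 0.00137).

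**Figure D2:**
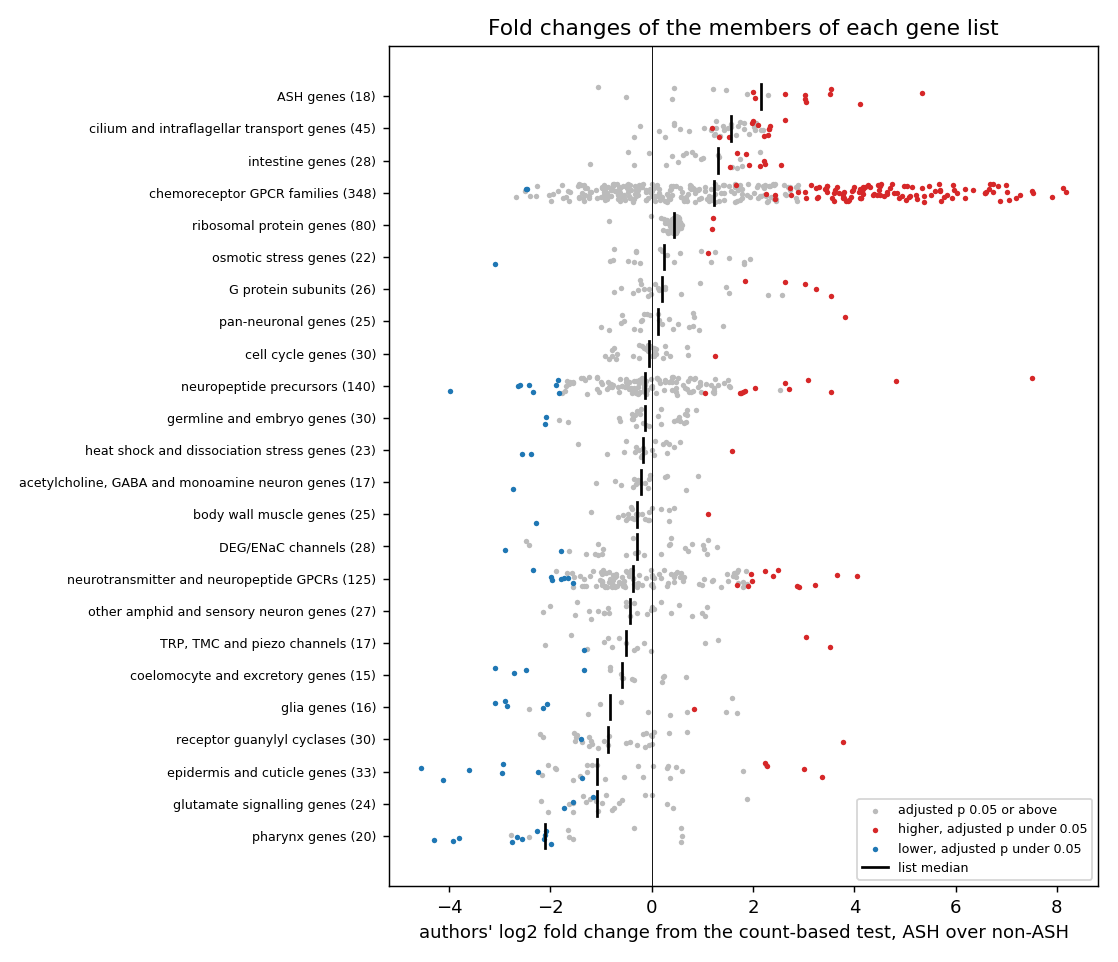
Authors' log2 fold change from the count-based test, ASH over non-ASH (horizontal), of each tested member of the 24 gene lists (rows, tested members in brackets), with 1 point per gene, colour for calls at an adjusted p under 0.05 and a black bar at the list median. The medians run from 2.16 for ASH genes to -2.11 for pharynx genes, and 112 of the 348 chemoreceptor genes are marked as higher.

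Markers of other tissues moved in different directions between the fractions. Intestine genes were higher in ASH, with 8 of 28 past the threshold and 0 lower (Fisher's exact adjusted p = 0.000716; 10 higher adjusted over the list alone), 24 with a positive fold change and a median of 1.31. They included the desaturase gene fat-6 at 568 FPKM against 162 (log2 fold change 1.91), the GATA factor gene elt-2 (1.67) and the protease gene asp-1 at 3660 against 692 (2.22), which Cuffdiff did not call (q = 0.111), in the authors' deposited table. The intestine count fell to 3 with an adjusted p under 0.01 (Fisher's exact adjusted p = 0.227). Pharynx genes were lower, with 11 of 20 past the threshold and 0 higher (Fisher's exact adjusted p = 3.43e-09; 15 lower adjusted over the list alone) and a median of -2.11. Besides phat-3 and phat-4, the myosin gene myo-5 had a log2 fold change of -2.77 in the authors' deposited table. Epidermis and cuticle genes split, with 7 of 33 lower (Fisher's exact adjusted p = 0.00352) and 4 higher (Fisher's exact adjusted p = 0.355), and with 12 lower and 6 higher adjusted over the list alone. The lower count did not pass with an adjusted p under 0.01 (3 genes, Fisher's exact adjusted p = 0.227) or among genes above the median level (2 genes, 0.331), and the higher count passed with Cuffdiff's q (5 genes, 0.0238) and by both tools (4 genes, 0.0319). The collagen genes dpy-13 (-4.56) and col-12 (-4.12) were lower and the collagen gene dpy-17 (3.35) was higher in the authors' deposited table. Glia genes had 5 of 16 lower and 1 higher (Fisher's exact adjusted p = 0.00352 for lower; 6 and 2 adjusted over the list alone), among them fig-1 (-3.09), vap-1 (-2.14) and T02B11.3 (-2.06) in the authors' deposited table. With Cuffdiff's q, 2 glia genes were lower (Fisher's exact adjusted p = 0.323), and fig-1 was not among them. The lower count of glia genes also did not pass by both tools (Fisher's exact adjusted p = 0.195) or above the median level, where 1 of 2 tested was lower (0.331), and the list median of -0.81 lay at the 2.05 percentile of random lists (adjusted p = 0.0761). Coelomocyte and excretory genes had 4 of 15 lower (Fisher's exact adjusted p = 0.0213; 4 adjusted over the list alone), with the coelomocyte genes cup-4 (-3.10), lgc-26 (-2.49) and unc-122 (-2.71) leading in the authors' deposited table. Their median of -0.58 lay at the 3.57 percentile of random lists (adjusted p = 0.123).

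Body wall muscle genes were slightly lower in ASH as a list, with 20 of 25 fold changes negative and a median of -0.29 against 0.19 for the random lists (0.2 percentile, adjusted p = 0.0101). Singly, 1 was higher and 1 lower, also adjusted over the list alone. The myosin gene unc-54 had 1.11 and the troponin gene tnt-3 had -2.29 in the authors' deposited table. Germline and embryo genes had 2 of 30 lower and 0 higher, also adjusted over the list alone, and a median of -0.14 at the 0.59 percentile (adjusted p = 0.024). Both were sperm protein genes, msp-19 (-2.08) and msp-78 (-2.10), in the authors' deposited table. Cell cycle genes had 1 of 30 higher, the linker histone gene his-24 (1.25 in the authors' deposited table), with the same count adjusted over the list alone and a median of -0.05.

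Ribosomal protein genes had a median of 0.45, quartiles of 0.41 and 0.50, and 78 of 80 positive fold changes, while random lists of the same levels had a median of 0.32 (99.9 percentile, adjusted p = 0.006). Only rpl-25.1 (1.18) and rpl-11.2 (1.21) passed the threshold singly in the authors' deposited table, 2 also adjusted over the list alone. Heat shock and dissociation stress genes did not move together, with 1 of 23 higher and 2 lower, also adjusted over the list alone, and a median of -0.17. These were jun-1, part of the AP-1 factor, at 1.59, the superoxide dismutase gene sod-3 at -2.55 and the glutathione transferase gene gst-4 at -2.39 in the authors' deposited table. Of 22 osmotic stress genes 1 was higher, the aquaporin gene aqp-2 (1.11), and 1 lower, the inositol transporter gene hmit-1.2 (-3.09), in the authors' deposited table (1 and 2 adjusted over the list alone). With Cuffdiff's q, 5 osmotic stress genes were higher (Fisher's exact adjusted p = 0.00549). The medians of 12 of the 24 lists did not pass the comparison with random lists (adjusted p from 0.0761 to 0.861), namely the lists of pan-neuronal genes, transmitter and neuropeptide receptors, G protein subunits, TRP and DEG/ENaC channels, other sensory neurons, other transmitters, glia, coelomocytes, heat shock, osmotic stress and the cell cycle. Fisher's exact test and the random lists treat the genes of a list as independent, which co-regulated genes are not, so these p are too small to an unknown degree.

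The 2 tools ordered genes alike and differed in which they called. Across the 16802 genes with both, the log2 fold changes of the authors' deposited table correlated with a Pearson r of 0.915 and a Spearman rho of 0.955, as a description across genes, which are not independent replicates. At thresholds of 0.05, DESeq2 called 894 genes higher and Cuffdiff 601, and 397 were shared where 31.98 would be shared by independent lists. For lower genes the counts were 746 and 593 with 376 shared, against 26.3 for independent lists, and 0 genes were called in opposite directions. Both tools used the same libraries, so an overlap above that of independent lists is built in and is no separate support for the calls. Over all genes with a Cuffdiff q, that tool called 614 higher and 606 lower in the authors' deposited table. Chemoreceptor genes were the clearest case of a difference: Cuffdiff called all 16 of those that DESeq2 placed higher and that were listed at 0 FPKM in non-ASH, and 0 of the 68 listed above 0 and under 0.2 FPKM there, in the authors' deposited table.

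**Figure D3:**
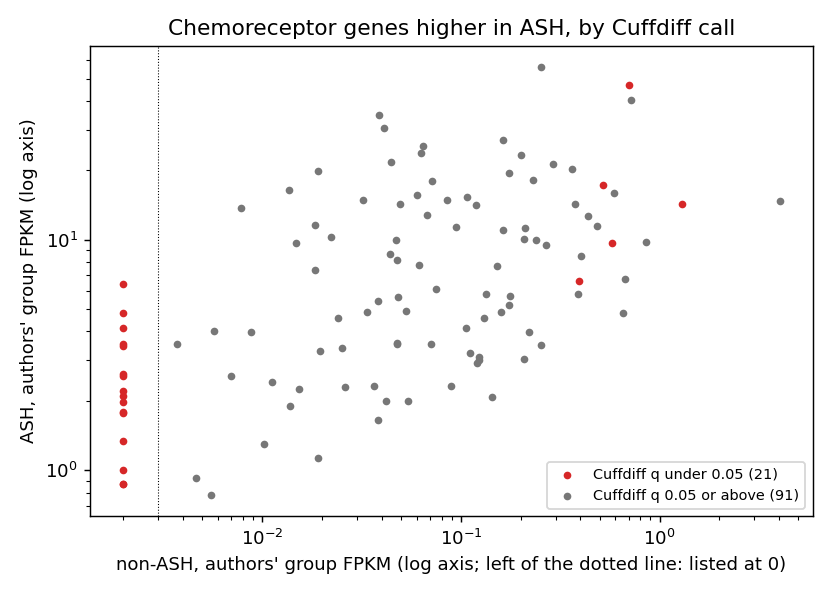
Authors' group FPKM in ASH (vertical) against non-ASH (horizontal), both on log axes, for the 112 chemoreceptor genes that were higher in ASH, with 1 point per gene and red for the 21 that Cuffdiff also called. The 16 genes listed at 0 in non-ASH, drawn left of the dotted line, are all red, and the 68 between 0 and 0.2 FPKM are all grey.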

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

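The genes described here were singled out after the data were seen. A signal outside the main measurement came from genes that have no DESeq2 adjusted p and still pass Cuffdiff's threshold, 13 higher and 13 lower in ASH in the authors' deposited table. Of these 26 genes, 21 have a fold change and no p and 5 have a p and no adjusted p. By default DESeq2 leaves the p blank for a gene with an extreme count in a library. The values of these 21, with ins-14, tmem-145 and clec-190 among them, may therefore rest on single libraries. The higher genes include the insulin-like gene ins-14 at 117 FPKM in ASH against 13.4 in non-ASH and C15A7.2, now tmem-145, at 17.4 against 0.817, and the lower genes include the lectin gene clec-190 at 0.536 against 105.5 in the authors' deposited table. Of the 13 higher genes, 6 were listed at 0 FPKM in non-ASH, namely srw-67, srh-278, T05C7.5, sru-14, nhr-218 and fbxb-76. In ASH, nhr-218 stood at only 0.396 FPKM in the authors' deposited table. Cuffdiff also called every gene higher by DESeq2 and listed at 0 there, so these 6 calls may rest on the exact 0. No biological explanation was tested.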

How the results depend on the processing

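No paired analysis was possible because the table gives 1 value per group and no value per library. For the same reason leaving out libraries, a fit with the replicate number as a term, other normalizations, filters on counts and tests with a correlation between genes were not run, and the depth that limits low genes is unknown. Alternatives for lists other than 2-fold and the background above the median level, and calls by both tools, were chosen after the data were seen.

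The counts of 894 higher and 746 lower genes stayed within 1.5 times under 2-fold (823 and 685), Cuffdiff's q (614 and 606), a floor of 5 FPKM (718 and 563), protein-coding genes (859 and 741) and without chemoreceptor genes (782 and 744). They were 449 and 346 with an adjusted p under 0.01, and 397 and 376 by both tools. Of Cuffdiff's calls, 397 and 376 were shared with DESeq2's. With both thresholds at 0.01 the tools shared 165 higher and 165 lower genes.

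At an adjusted p under 0.01 the lists held 6 ASH genes, 2 cilium genes, 3 intestine genes, 3 lower epidermis genes and 3 lower glia genes, and the cilium, intestine and epidermis calls were lost. Above the median level there were 4 higher ASH genes, 28 chemoreceptors and 6 transmitter and peptide receptors, all past the threshold, and 2 cilium, 2 lower epidermis and 1 lower glia genes, no longer past it. Those losses go with fewer genes tested, 4, 11 and 2.

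With a floor of 5 FPKM, 7 cilium genes, 60 chemoreceptors and 2 lower glia genes kept their calls, and 8 higher and 6 lower transmitter and peptide receptors, 5 G protein subunits and 3 lower glutamate genes gained one. Cuffdiff's q gave 29 chemoreceptors, called, and 2 lower glia genes, not called. It added calls for 12 transmitter and peptide receptors, 5 G protein subunits, 14 neuropeptides, 5 higher epidermis genes and 5 osmotic stress genes. By both tools there were 6 cilium genes and 21 chemoreceptors, called, 2 lower glia genes, not called, and new calls for 9 receptors, 4 G protein subunits, 9 neuropeptides and 4 higher epidermis genes. At 2-fold, 5 G protein subunits passed. The cause was not tested where none is given. The calls of ASH genes, chemoreceptor genes, lower pharynx genes and lower coelomocyte genes held in all of these settings, and no call changed when lists were matched on the names in the table only. For chemoreceptor genes these settings are not independent support. Of the 21 called by both tools, 16 were listed at 0 FPKM in non-ASH, and Cuffdiff called all higher genes listed so. The floor of 5 FPKM and the median level admit genes near 0 in non-ASH only through their ASH level.

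Of the 89 named genes, 22 lost their call with Cuffdiff, 1 (gpa-3) gained one and 66 kept their side, with 0 changes of direction. The ratio of FPKM, on the linear scale, moved by over 1.5 times for 37 with a pseudocount of 0.1 and for 51 with 5.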

Other observations

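All tests in this part, and the genes named in it, were chosen after the data were seen. Families sharing a name stem with at least 10 tested genes, 154 in all, were compared with other tested genes by Fisher's exact test, adjusted over both directions. Outside the chemoreceptors, skr genes, related to Skp1 of ubiquitin ligases, had 8 of 20 higher (Fisher's exact adjusted p = 0.000195), transthyretin-related ttr genes 11 of 55 (0.00299), saposin-like spp genes 7 of 24 (0.00377), neuropeptide-like nlp genes 12 of 69 (0.00462) and aspartyl protease asp genes 5 of 13 (0.00615). Of these families, 5 ttr, 3 nlp and 2 spp genes were lower. The families osm, dyf and dct also passed as higher (Fisher's exact adjusted p from 0.00247 to 0.0476). Of the spp genes, spp-14 stood at 1612 FPKM in ASH against 347 in non-ASH in the authors' deposited table. Lower in ASH were 36 of 136 collagen genes named col (Fisher's exact adjusted p = 2.14e-16), 18 of 32 major sperm protein genes named msp (9.93e-15), 7 of 15 nspc genes (7.99e-05) and 8 of 40 glutathione transferase genes named gst (0.00541). The families pqn, srlf, idpp, fipr and grd also passed as lower (Fisher's exact adjusted p from 0.00196 to 0.0359). In the other direction, 3 gst, 2 pqn, 2 srlf, 2 fipr and 1 col genes were higher. Near-identical members of the msp and col families are uncertain where reads are shared among them.

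Within the chemoreceptors, srh genes had 28 of 53 higher (Fisher's exact adjusted p = 1.1e-19), srw 17 of 26 (2.9e-14) and srx 14 of 34 (4.17e-08); sri, sru, sra, srsx and srv genes also passed (Fisher's exact adjusted p from 0.00191 to 0.0285), while the families str with 4 of 36 (0.699), srd with 4 of 25 (0.352), sre with 3 of 21 (0.628), srg with 1 of 20 (1) and srt with 1 of 17 (1) did not pass. These family shares are of tested members only. For genes near 0 in non-ASH being tested goes with the ASH level, so the family p are only descriptive. Chromosome V held 232 higher genes among 3255 tested (7.13%, Fisher's exact adjusted p = 2.84e-06), but once chemoreceptor genes were set aside chromosomes V (5.57%), II (5.58%) and X (5.66%) each had a Fisher's exact adjusted p of 0.0366. Lower genes were more frequent than elsewhere on X (144 of 2274, Fisher's exact adjusted p = 2.63e-05), IV (146 of 2627, 0.00558) and V (172 of 3255, 0.012). The TRP channel gene ocr-1 was listed at 220 FPKM in ASH against 41.5 in non-ASH while its DESeq2 log2 fold change was -2.11 (adjusted p = 0.0821) in the authors' deposited table, so the tools gave it opposite directions and neither called it.

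Most chemoreceptor genes higher by DESeq2 were not called by Cuffdiff. That the genes not called were the weaker ones in ASH is argued against as the whole cause. Over all members the 91 not called had a median of 7.38 FPKM in ASH and the 21 called 2.62. The difference in median log2(FPKM + 1) was 1.21. Of the 21 called, 16 were listed at 0 in non-ASH, with a median of 2.16 FPKM in ASH. The 68 listed above 0 and under 0.2 FPKM in non-ASH, 0 of them called, had a median of 5.31. Among members listed above 0 in non-ASH the question stays open. There the median log2(FPKM + 1) in ASH of the 91 not called minus that of the 5 called was -0.87 (medians 7.38 and 14.3 FPKM, exact rank-sum test, 2-sided, p = 0.0867). An effect of an exact 0 in non-ASH also stays open as a candidate explanation: Cuffdiff called 16 of 16 genes listed at 0 and 0 of 68 listed above 0 and under 0.2 FPKM (Fisher's exact test, 2-sided, p = 1.57e-17). Other higher genes showed the same split, with 4 of 4 and 7 of 58 (Fisher's exact test, 2-sided, p = 0.000592). No biological explanation was tested.

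The higher level of many chemoreceptors in ASH was set against an even background, such as genomic DNA, that lifts silent genes in the ASH libraries. An even background as the whole cause is argued against, since among protein-coding genes under 0.2 FPKM in non-ASH 100 of 1086 chemoreceptors (9.21%) and 177 of 3148 other genes (5.62%) exceeded 1 FPKM in ASH (Fisher's exact test, 2-sided, p = 6.4e-05), while 81.5% and 77.95% stayed under 0.2; gene length was not matched, the shares had been seen before this test was chosen, and it replaced 2 earlier tests that also argued against such a background but were unsuited, a comparison with the reverse share in other genes (8.49%) and one with the levels of chemoreceptors selected as higher, so its p is only descriptive. An uneven background or reads shared with close copies stay open. Among tested members, chemoreceptor pseudogenes were higher more often than protein-coding ones (16 of 32 against 96 of 316, Fisher's exact test, 2-sided, p = 0.0291), although 9 of 453 other pseudogenes were. That difference cannot decide, because for genes near 0 in non-ASH being tested goes with the ASH level. Of all 1632 chemoreceptor rows 1344 are protein-coding, so most untested rows are too. Whether 1 or a few ASH libraries carried these transcripts cannot be told apart from expression in all, because no value per library was at hand. Of the 1236 chemoreceptor genes with a fold change 24.2% had no p, against 11.04% of the 7553 other such genes in their range of levels. By default DESeq2 leaves the p blank for a gene with an extreme count in a library. Single libraries may therefore weigh more on chemoreceptors than on other genes. The genes called higher all have a p and lie outside that share. Expression of many receptor genes in ASH itself, the difference the sort was made for, stays open.

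Marker lists of other tissues moved apart between the fractions. A lower share of 1 cell type, raising all others alike, is argued against by the difference of 1.60 between the median log2 fold changes of intestine and body wall muscle genes (permutation test, 2-sided, p = 2e-05). A lower share of muscle alone would give that difference, but pharynx genes would then also exceed muscle genes. Their median minus that of muscle genes was -1.82 (permutation test, p = 0.00017). Permutation treats co-regulated genes as independent, so both p are only descriptive. RNA or cells of other types in the ASH fraction may contribute. The median body wall muscle gene stood at 81.8% of its non-ASH level and the median germline and embryo gene at 90.6%, although the sort should remove both. Pan-neuronal genes were not higher as a group, with a median log2 fold change of 0.12. The other tissue lists lay further from their non-ASH level, with medians from -2.11 for pharynx genes to 1.31 for intestine genes. More intestinal cells or their RNA among the sorted ASH cells are a candidate source, as 11 of 12 intestine genes of at least 100 FPKM in non-ASH had a positive fold change, 5 of them past the threshold; the abundant far-2 (-0.47) and the less abundant act-5 (-1.22) went the other way in the authors' deposited table. None of the intestine genes is held by another list. A gate on YFP is meant to remove cells without it, but how well it excluded intestinal cells cannot be read from these values. A rise of these genes within ASH was not tested.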
